A study of Xenopus andrei with 9 samples.

How the data were processed

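RNA was measured in 9 libraries of the frog Xenopus andrei, a polyploid relative of the laboratory frog Xenopus laevis, at 1 library per developmental stage. Each library was made from a pool of 5 individuals, and all of them came from 1 mating. Stages are those of Nieuwkoop and Faber, whose table numbers the steps of Xenopus development, and stage 0 is the unfertilized egg. Per the labels' protocols, embryos were kept at 22 °C in 0.1-fold Marc's Modified Ringers, a frog saline, with gentamicin at 50 µg/ml, pools were frozen in liquid nitrogen, and stranded Illumina libraries were prepared after ribosomal RNA had been depleted. Ribosomal depletion keeps transcripts without a poly(A) tail, so unspliced and histone RNAs are not removed by design.

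The authors deposited 1 table of TPM, an abundance corrected for transcript length and scaled to a fixed total per library. Its rows carry names in the form that the Trinity assembler gives to assembled transcripts (contigs), which state a component, a Trinity gene and an isoform. The submitters' processing notes name FastQC, Trimmomatic 0.36 and Salmon 0.8.2. Trimmomatic trims reads, and Salmon estimates transcript abundance and divides reads that match several transcripts between them. The assembler settings, the libraries that went into the assembly and any filter on contigs are not given in the sources used here. Each deposited column of TPM sums to the same total over 1650048 contigs, so a contig's value depends on everything else listed in its library. The column names matched the sample labels apart from the case of 1 letter. The table holds no gene names, sequences or positions, so results are given for contigs and groups of contigs. The 28 gene lists fixed in advance, and the planned tests of list trends, Hox gene order and homeolog balance, were not analysed here for that reason. The rule for named contigs was, without gene symbols, the 2 contigs that rose and the 2 that fell most steeply among called trends with a mean of at least 10 TPM.

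TPM keeps no absolute depth, so the number of reads behind a value is unknown and no counting interval is given. Relative depth was estimated from what 1 read is worth. For 1 contig, the TPM of 1 read in a library relative to stage 40 is the same for all contigs up to effective length, so the log2 ratio of values below 1 TPM has a sharp mode. The median ratio within 0.02 log2 of that mode was used. On 300000 simulated contigs at 3 known depths, the largest error was 0.133%. The simulated libraries shared their abundances and contig lengths and held whole reads. Their error therefore does not cover libraries as unlike as eggs and stage 40. Of the egg ratios, 6.79% lay at the mode, against 11.9% to 15.1% for stages 10 to 38. The estimate counts each read divided by contig length, so it equals a ratio of read numbers only where lengths are alike. Relative depth was 66.2% of stage 40 in eggs, 81.6% at stage 10, 83.3% at stage 12, 88.1% at stage 18, 92.3% at stage 25, 102.2% at stage 30, 102.9% at stage 35 and 106.6% at stage 38.

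Comparisons of 2 stages rest on 1 library each, so they have no replicate check and no p-value. A difference was counted when (TPM + 1) differed at least 4-fold, over the 111344 contigs with a mean of at least 1 TPM across the 9 libraries. Libraries were compared by Spearman's rho across the same contigs, which are not independent replicates. The only test was a straight-line trend of log2(TPM + 1) on stage number, fitted with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Its error is the scatter of 9 libraries around the line. The p-values therefore cover these 9 pools from 1 mating, not other matings, and a change far from a straight line can be missed. A fold on the log2(TPM + 1) scale understates the change of low contigs. In simulated data with the scatter of the real contigs, 200 contigs among 111344 were changed. The trend test recovered 42.4% of changes of 4 log2 units between stages 0 and 40, 4.55% of changes of 2 units and none of 1 unit. There were 3 false calls. With so few changed contigs the adjustment is stricter than in the real data, which gave 33029 calls, so these shares do not give the recovery there. Of the real calls, 8167 rises and 8833 falls were of at least 2 units, and the rest were smaller.

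Contigs at 5 TPM or more in eggs were followed to later stages, contigs below 1 TPM in eggs were dated by the first stage at 5 TPM or more, and contigs that peaked between egg and stage 40 were counted. These 3 summaries were chosen after the data had been seen. The other comparisons and their alternatives were fixed before the data were examined, apart from some descriptive values. Not in that plan were relative depth, counts at 100 TPM or more, shares of TPM by contig level and the effective number of contigs. The breakdown of called trends by mean level and by values in eggs and late stages was not in it either. Alternatives were pseudocounts of 0.1 and 10, no filter or a mean of at least 5 TPM, scaling by the median ratio over 28062 contigs at 1 TPM or more in every library, TPM recomputed without the 10 highest contigs, the rank of the stage, a Spearman test with an exact permutation p, and leaving out each stage. Added after the data had been seen were sums per Trinity gene (1023069 genes) and 3 fits that use the number after the hyphen in the library names. That number is 1 for stages 10, 12 and 30 and 2 for the others, and its meaning is not given in the sources used here. Median-ratio scaling divided the TPM by 1.78 in eggs and by 0.78 at stage 40. The thresholds and the pseudocount were left unchanged on the rescaled values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for all other steps.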

Results

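The transcriptome of X. andrei was sampled once at each of 9 points of early life. These were the unfertilized egg (stage 0), the gastrula (stages 10 and 12), the neurula (stage 18), and tailbud embryos and tadpoles (stages 25, 30, 35, 38 and 40). Of 1650048 assembled contigs, 103509 were listed above 0 TPM in all 9 libraries and 54459 in none. There was 1 library per stage, so single-stage values carry no error and differences between 2 stages were not tested.

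The egg library listed fewer contigs than any embryonic library, and more of them at moderate TPM. Eggs listed 267970 contigs above 0 TPM, stage 10 listed 612341, and stage 40 listed 938766, which was 3.50-fold more than eggs. At a higher level the order was the opposite. Eggs had 42831 contigs at 5 TPM or more, 2.80-fold more than the 15298 at stage 40, with 23612 at stage 10. With median-ratio scaling this second difference was small, with 22071 contigs at 5 or more in eggs and 21060 at stage 40. At 100 TPM or more the libraries were close, with 423 contigs in eggs and 430 to 513 at the later stages. The number of contigs at 1 TPM or more was 137615 in eggs and between 163454 and 172557 later. Estimated relative depth was lowest in eggs, at 66.2% of stage 40.

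The share of RNA held by low contigs differed in the same way. Contigs below 1 TPM held 5.48% of all TPM in eggs, 19.2% at stage 10, 24.3% at stage 12 and 28.7% to 33.5% from stage 18 on. Contigs from 5 to below 50 TPM held 48.3% in eggs, 26.0% at stage 10 and 16.7% at stage 40. Contigs at 50 TPM and over held 24.0% in eggs and 24.6% at stage 40. The 1000 highest contigs of each library, a planned measure, held 22.2% in eggs, 26.0% at stage 12 and 24.1% at stage 40. The effective number of contigs, which is the number of equally abundant contigs with the same Shannon entropy, was 50454 in eggs, 80805 at stage 10 and 147908 at stage 38, and was lower again at stage 40, at 119561. The contig with the highest mean stood at 3457 TPM in eggs and 52943 TPM at stage 40, where it alone made up 5.29% of the library.

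**Figure D1:**
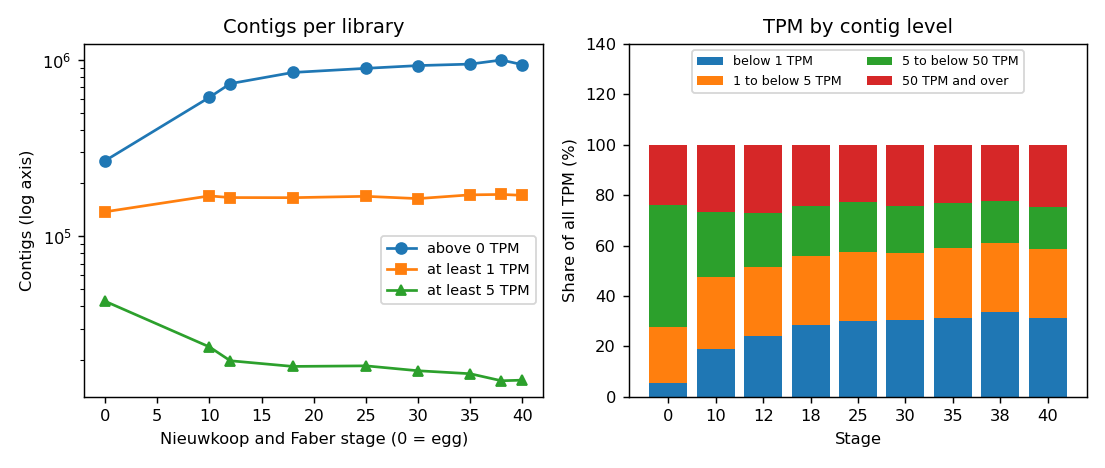
Left, number of contigs per library (log axis) above 0, at 1 or more and at 5 TPM or more, against Nieuwkoop and Faber stage. Right, percent of each library's TPM held by contigs of 4 level classes; contigs below 1 TPM hold 5.48% in eggs and 31.3% at stage 40.

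The libraries fell along the order of development, with the egg standing apart. Across 111344 contigs with a mean of at least 1 TPM, Spearman's rho was 0.44 between egg and stage 10, 0.21 between egg and stage 12, and 0.08 to 0.13 between egg and any stage from 18 on. The gastrula libraries of stages 10 and 12 correlated at 0.69, and stage 12 and the neurula at 0.67. From stage 25 to stage 40 all pairs of libraries lay between 0.68 and 0.78. Among these, stages 25 and 40 were the least alike (0.68) and stages 35 and 38 the most alike (0.78). At a mean of at least 5 TPM, rho between egg and stage 40 was -0.043, against 0.10 over all contigs compared. Contigs were chosen by their mean over the same libraries, which leaves out those low in both. The filter can itself lower rho between unlike libraries, so the change of sign is not a finding about the stages.

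**Figure D2:**
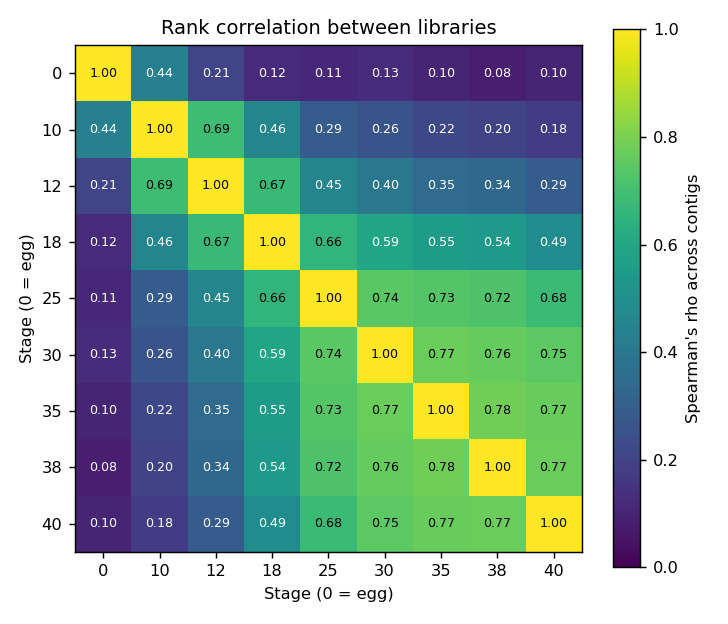
Spearman's rho between each pair of the 9 libraries, across 111344 contigs, with stage numbers on both axes. Pairs within stages 25 to 40 lie between 0.68 and 0.78, and pairs with the egg between 0.08 and 0.44.

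The comparison of egg and stage 10 sets maternal RNA, laid down before fertilization, against the RNA of an embryo that has begun its own transcription. Of the 111344 contigs, 8446 were at least 4-fold higher at stage 10 and 10645 at least 4-fold lower, together 17.1%. This balance was not stable: after median-ratio scaling 7640 were higher and 4264 lower, and after summing per Trinity gene 8341 were higher and 7570 lower. The median contig was 0.25 log2 units lower at stage 10 in TPM as deposited, and at 0 after median-ratio scaling. All such counts depend on the pseudocount, and here the balance turned as well: 22261 contigs were higher and 20811 lower with a pseudocount of 0.1, and 506 and 394 with 10.

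Most abundant egg contigs were still present in the gastrula, though at lower TPM. Of the 42831 contigs at 5 TPM or more in eggs, 82.2% were at 1 TPM or more at stage 10, 70.9% at stage 12 and 68.5% at stage 40. The share that was still at 5 TPM or more was 36.7% at stage 10, 27.1% at stage 12 and 20.01% at stage 40. With median-ratio scaling it was 48.8%, 40.7% and 38.6%, and per Trinity gene 50.1%, 40.7% and 35.3%. The share listed at 0 was 4.07% at stage 10 and 7.11% at stage 40 (1.71% and 4.48% of the contigs at 5 or more with median-ratio scaling). The same count between later neighbours served as a reference: of contigs at 5 TPM or more, 96.4% were at 1 TPM or more from stage 10 to stage 12, and 99.1% from stage 38 to stage 40. Of the egg contigs, 17014 were below 1 TPM at some point between stages 10 and 18, and 567 of these (3.33%) were at 5 TPM or more again between stages 35 and 40. With median-ratio scaling, which puts 22071 egg contigs at 5 or more, 88.7% were at 1 or more at stage 10 and 84.0% at stage 40; 489 of 5838 (8.38%) then returned, and 515 of 8809 (5.85%) did so after summing per Trinity gene.

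Contigs that were absent or low in eggs appeared mostly by the neurula. There were 13894 contigs below 1 TPM in eggs that reached 5 TPM later, and 11231 of them were listed at 0 in eggs. The first stage at 5 TPM or more was stage 10 for 4975 contigs (35.8%), stage 12 for 2552 (18.4%), stage 18 for 2130 (15.3%) and stage 25 for 1838 (13.2%). Stages 30, 35, 38 and 40 added 801, 640, 362 and 596 contigs. With median-ratio scaling stage 35 added 1095, stage 38 added 1086 and stage 40 added 1379, and stage 10 remained first with 4108. There the cutoff of 5 stands for less deposited TPM at late stages, and that of 1 for more in eggs. The larger late numbers can therefore come from the cutoffs. Seen from stage 10, 16.3% of its 23612 contigs at 5 TPM or more were listed at 0 in eggs, whereas 0.294% of such contigs at stage 40 were listed at 0 at stage 38.

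**Figure D3:**
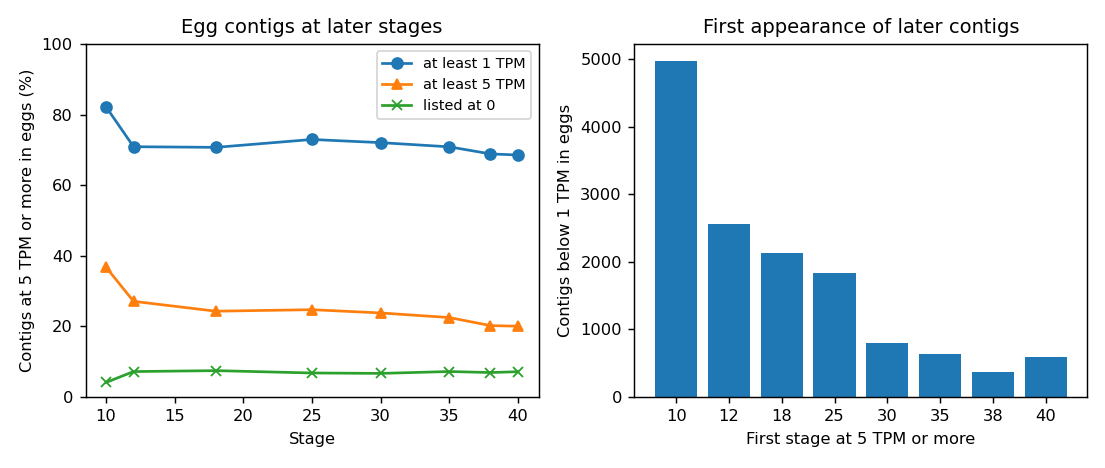
Left, percent of the 42831 contigs at 5 TPM or more in eggs that were at 1 TPM or more, at 5 TPM or more, or listed at 0 at each later stage; the upper line goes from 82.2% at stage 10 to 68.5% at stage 40. Right, number of contigs below 1 TPM in eggs by the first stage at 5 TPM or more, highest at stage 10 (4975).

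After gastrulation began, the difference between neighbouring libraries was smaller. Between stages 10 and 12, 2881 contigs (2.59%) differed at least 4-fold, and 56.0% of these were higher at stage 12. Between stages 12 and 18 the number was 2336, and between stages 18 and 25 it was 1977, of which 63.3% were higher at the later stage. Between stages 25 and 30, 939 contigs differed. The last 3 steps had 596, 557 and 609 contigs, or about 0.50% to 0.55% of those compared, with 45.2% to 50.2% of them higher at the later stage. The steps are not equal in time, and part of each count is the unmeasured spread between pools. Summing per Trinity gene gave 1272 between stages 18 and 25, 463 between stages 25 and 30, and 281, 256 and 281 for the last 3 steps. Median-ratio scaling gave 762, 893 and 1076 for these 3, with late values raised against an unchanged pseudocount.

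**Figure D4:**
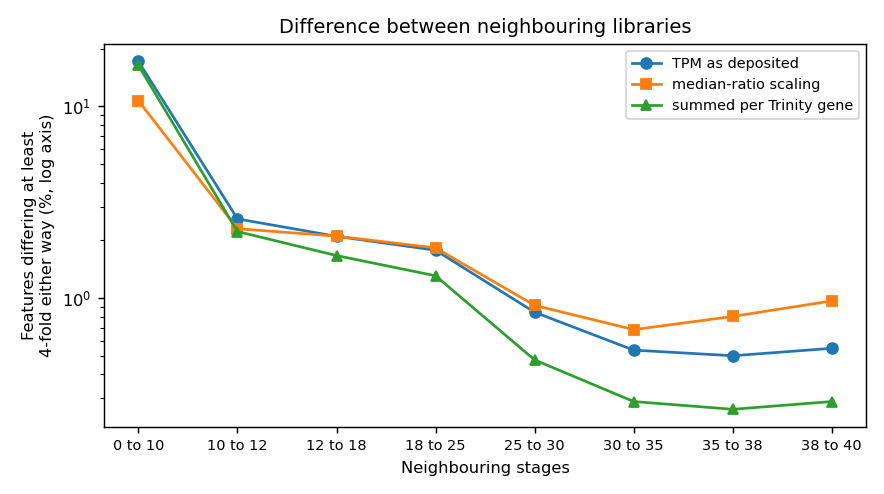
Percent of features (contigs, or Trinity genes for the third line) that differed at least 4-fold either way between neighbouring stages, on a log axis. In TPM as deposited the share is 17.1% from egg to stage 10 and 0.547% from stage 38 to stage 40.

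A set of contigs was transient, peaking between the egg and stage 40. There were 4656 contigs that reached 5 TPM and stood at least 4-fold, on (TPM + 1), above both egg and stage 40. Their peak was at stage 10 for 2137, stage 12 for 1575, stage 18 for 532 and stage 25 for 253. Peaks at stages 30, 35 and 38 were few, with 55, 55 and 49 contigs. The definition leaves little room for late peaks, since they must stand 4-fold above stage 40. Stages 35 and 38 each correlated with stage 40 at 0.77. With median-ratio scaling 3828 contigs were transient, 1304 of them with a peak at stage 10, 1522 at stage 12 and 155 at stage 38, so the order of stages 10 and 12 turned, and summing per Trinity gene gave 3344. Over all 111344 contigs, the highest value fell in eggs for 48283 (43.4%), at stage 10 for 14088 (12.7%) and at stage 40 for 7010 (6.30%). With median-ratio scaling eggs held the peak of 29534 and stage 40 of 15279. Contigs that peaked in eggs at least 4-fold above every other library numbered 4674 (1264 with median-ratio scaling), against 201 at stage 10, 38 at stage 12 and at most 12 at any later stage. This contrast depends on the stages sampled. The library nearest to the egg was stage 10 (rho 0.44), whereas stages 38 and 40 correlated at 0.77. The contigs compared also held 81.2% of the TPM in eggs, 66.9% at stage 10 and 56.8% at stage 40, so the filter favoured egg contigs.

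From egg to stage 40, 9301 contigs were at least 4-fold higher at stage 40 and 19115 at least 4-fold lower, together 25.5% of those compared. With median-ratio scaling the balance turned, with 14027 higher and 6017 lower. The scaling moves the whole distribution: the median ratio factor of stage 40 was 0.44 of that of eggs, and the median log2 ratio of all contigs went from -0.49 to 0.22.

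A straight-line trend over the 9 stages was called in 33029 of 111344 contigs by limma at an adjusted p below 0.05. Of these, 12809 rose and 20220 fell. Such a call does not show that the change was gradual. Among contigs that rose, 73.8% were listed at 0 in eggs and 67.5% had their highest value at stage 35, 38 or 40. Among contigs that fell, 79.2% were highest in eggs and 8.97% were listed at 0 at stage 40. The median fitted change from stage 0 to stage 40 was 2.25 log2 units for those that rose and -1.90 for those that fell, on the log2(TPM + 1) scale. In TPM as deposited, falls outnumbered rises in every class of mean level below 50 TPM. The numbers were 6231 against 5577 from 1 to below 2 TPM, and 8453 against 3987 from 2 to below 5 TPM. They were 3499 against 1505 from 5 to below 10 TPM, and 1804 against 1381 from 10 to below 50 TPM. Rises outnumbered falls at 50 TPM and over (359 against 233). The share that rose was 38.8% of calls in TPM as deposited and 71.0% with median-ratio scaling (19467 rose and 7952 fell), and after summing per Trinity gene 13412 rose and 13746 fell. With no filter on low values 5740 rose and 3140 fell among 1595589 contigs, so the balance turned there too, and the exact Spearman test called 6309 rises and 12459 falls. In the 6 libraries whose names end in 2, 8766 rose and 19087 fell, and with the ending as a term 12409 rose and 22988 fell. In the 3 libraries whose names end in 1 (stages 10, 12 and 30), 318 rose and 224 fell, and 374 of these calls were shared with the 33029. Without the egg library, 13778 rose and 19232 fell, and 20416 of the 33029 calls were shared.

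The steepest rises were of 2 contigs that were listed at 0 until stage 12 and came up in the neurula. TRINITY_DN258600_c3_g1_i2 stood at 4.51 TPM at stage 18, 197 TPM at stage 25 and 612 TPM at stage 40, with a fitted change of 11.55 ± 1.19 log2 units (SE; limma adjusted p = 0.000389). TRINITY_DN265517_c2_g1_i2 stood at 14.8 TPM at stage 18, 142 TPM at stage 25 and 567 TPM at stage 40, with a fitted change of 11.21 ± 1.05 (SE; limma adjusted p = 0.000364). The steepest falls were of 2 contigs that were abundant in eggs. TRINITY_DN288364_c4_g4_i1 was kept into the gastrula, with 145 TPM in eggs, 116 TPM at stage 10 and 65.2 TPM at stage 12, then 15.5 TPM at stage 18, 1.00 TPM at stage 25 and 0.0828 TPM at stage 40, with a fitted change of -8.60 ± 0.83 (SE; limma adjusted p = 0.000367). TRINITY_DN240829_c0_g2_i4 was lost earlier, with 486 TPM in eggs, 31.8 TPM at stage 10, 14.3 TPM at stage 12 and 1.54 TPM at stage 18, and was listed at 0 at stages 25, 35, 38 and 40; its fitted change was -8.27 ± 1.15 (SE; limma adjusted p = 0.000955). Fitted changes of contigs listed at 0 depend on the pseudocount.

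**Figure D5:**
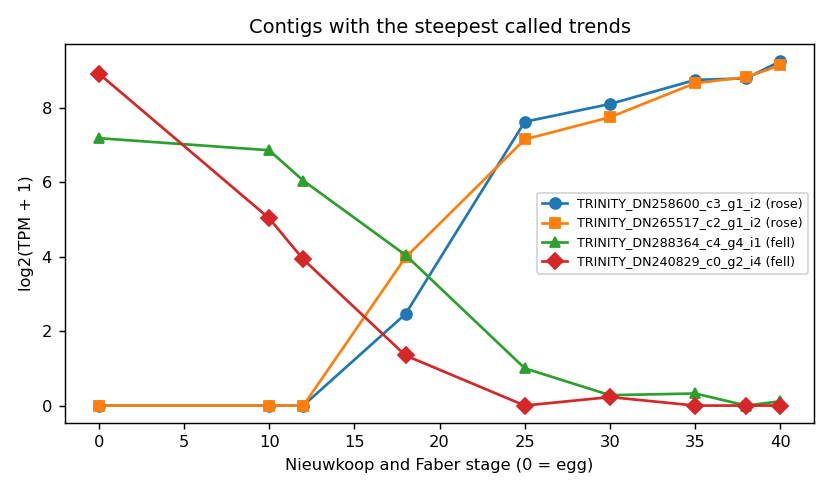
log2(TPM + 1) of the 4 contigs with the steepest called trends against stage, 1 library per point. The contigs that rose are at 0 until stage 12 and at 612 and 567 TPM at stage 40; those that fell start at 145 and 486 TPM.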

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

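The balance between rises and falls turned with median-ratio scaling, from egg to stage 10 also with either pseudocount and with sums per Trinity gene, and in the stage trend also with no filter and in the 3 libraries whose names end in 1. Counts of 4-fold differences depended on the pseudocount. Apart from the tests of the egg to stage 10 balance given below, the causes were not tested. No result could be checked against replicates, and TPM gives no absolute depth, so the precision of low contigs is unknown. The order of the steps kept egg to stage 10 as the largest in all 7 settings. The stage trend counted 5740 rises and 3140 falls with no filter (1595589 contigs tested), 3428 and 6079 at a mean of at least 5 TPM (19396 tested), 19467 and 7952 with median-ratio scaling (20761 calls shared with the 33029), 6309 and 12459 by the exact Spearman test, and 318 and 224 in the 3 libraries whose names end in 1, a fit with 1 residual degree of freedom per contig. Leaving out 1 stage gave 9968 to 13778 rises and 14456 to 23815 falls. The 4 named contigs kept their direction, with adjusted p of at most 0.034 in 19 alternative limma fits and at most 0.017 by the exact Spearman test; they were not followed in sums per Trinity gene. Egg to stage 10 gave 22261 higher and 20811 lower at a pseudocount of 0.1, 506 and 394 at 10, and 4264 lower with median-ratio scaling. Egg to stage 40 gave 30159 higher and 31435 lower at 0.1, 771 and 870 at 10, and 14027 and 6017 with median-ratio scaling. The 7 later steps, in order, gave 18979, 16204, 13442, 9044, 8201, 7985 and 8605 at a pseudocount of 0.1, 74, 81, 78, 15, 10, 11 and 9 at 10, and 5960, 4425, 3398, 2009, 1557, 1485 and 1631 with no filter. Median-ratio scaling gave 893 and 1076 for the last 2 steps, and sums per Trinity gene gave 1272, 463, 281, 256 and 281 for the last 5. At a mean of at least 5 TPM, rho was 0.46 between egg and stage 10, 0.91 between stages 38 and 40, and -0.043 between egg and stage 40, where the sign turned; Pearson's r was 0.49, 0.88 and 0.19. Eggs, stage 10 and stage 40 held 252250, 578860 and 890018 contigs at 0.1 TPM or more, and 42831, 23612 and 15298 at 5 TPM or more. At a mean of at least 5 TPM, 7522 contigs peaked in eggs, 1447 at stage 40 and 744 in eggs at least 4-fold above all others; median-ratio scaling gave 29534, 15279 and 1264. Egg contigs still at 1 or more at stages 10 and 40 came to 88.7% and 84.0% with median-ratio scaling, and 89.7% and 83.7% per Trinity gene. The alternative of summing TPM per gene symbol was not run, since contigs carry none. No paired analysis was possible because each stage has 1 library.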

Other observations

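The tests of depth, of low-level reads, of sums per Trinity gene and of the ratio of falls to rises were chosen after the results they bear on had been seen; the others were written beforehand.

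The TPM of contigs that the assembler put under 1 Trinity gene moved together over the stages. In 2249 Trinity genes with exactly 2 contigs at a mean of at least 5 TPM, the slopes over stage correlated across genes at 0.88, against at most 0.07 in 1000 shuffles of the pairs. Both contigs had a called trend in 786 of them, and only 8 (1.02%) went in opposite directions. Shuffled pairs gave 40.5% to 53.1%, so the values of such contigs did not behave like those of unrelated ones. Contigs of 1 Trinity gene may match the same reads, which Salmon divides, whereas shuffled partners do not. The shuffles therefore cannot tell shared reads from shared regulation. The deviations from the trend line also went together, with a median correlation of 0.76 over all pairs and 0.02 in shuffled pairs. For the 8 opposite pairs the median was -0.21 (quartiles -0.71 to -0.01). The rule written beforehand took a median below -0.2 as a sign of Salmon's division of reads between near-identical contigs, and it was just met. A condition that both quartiles lie on 1 side of that bound was not part of the written rule, and it was not met. With 8 pairs, such division of reads and a switch of isoforms or gene copies between egg and tadpole cannot be told apart.

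The number of contigs above 0 TPM was 3.50-fold higher at stage 40 than in eggs. The stage 40 count was multiplied by the estimated relative depth of eggs, 66.2%, as if every contig rested on 1 whole read. No reads were drawn. On that assumption 621709 contigs would remain, 2.32 times the number in eggs, so lower depth of the egg library would not account for the rise. Salmon divides reads, so a value above 0 can rest on less than 1 read. The count of 621709 is therefore not a firm lower bound, and a part played by depth is not excluded. The error of the depth estimate for libraries this unlike is not known. A candidate explanation is RNA from introns, unspliced transcripts or genomic DNA, which a growing number of nuclei could bring and which ribosomal depletion keeps. Of 740508 contigs at 0 in eggs and above 0 at stage 40, 35.6% reached 1 TPM and 1.34% reached 5 TPM in any library, as that hypothesis allows, but a broad low-level transcription of genes after the egg stage would give the same, and without sequences or positions these cannot be told apart. An assembly drawn mainly from later libraries was not tested.

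More contigs were 4-fold lower than higher at stage 10 relative to eggs, with a ratio of falls to rises of 1.26. The excess is not firm, since in TPM as deposited the ratio was 0.93 at a pseudocount of 0.1 and 0.78 at 10. With median-ratio scaling it was 0.56. That scaling removes a shift shared by the 28062 contigs at 1 TPM or more in every library, whatever its cause. It therefore cannot tell whether low contigs, which take up more of each later library, lowered the TPM of the others. Summed per Trinity gene the ratio was 0.91, so falls no longer outnumbered rises, as a split of reads between near-identical contigs would give. Summing also counts contigs of 1 Trinity gene that fall together as 1 feature, so the ratio cannot tell these apart. A change of pseudocount removed the excess as well.

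Contigs that fell 4-fold from egg to stage 10 were 34.0 times as many as from stage 38 to stage 40. The ratio depends on the pseudocount, with 20811 against 4838 falls at 0.1 and 394 against 5 at 10. Median-ratio scaling lowered the falls from 10645 to 4264 and raised those from stage 38 to stage 40 from 313 to 540, so the ratio became 7.90. The pseudocount stayed at 1 on the rescaled values, so the change of the ratio mixes the scale with the pseudocount. The 4264 falls that remained still exceeded the 540, so the shift that this scaling removes does not account for all of them. Summed per Trinity gene, falls were 47.9 times as many and changes either way 56.6 times as many, so neither does the division of reads within a Trinity gene. Clearance of maternal RNA and a difference between egg and embryo in total RNA stay open, as neither was measured.

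The count of 33029 called trends is not explained by a chance order of the libraries. Of 100 orders of the 9 stages, the real one included, 1 gave as many calls, and the highest of the others gave 3705. The test cannot tell changes of single contigs from a drift of the whole scale with stage. The median-ratio factor went from 1.78 in eggs to 0.78 at stage 40, and such a drift would pass as well. After median-ratio scaling, 20761 of the 33029 calls were shared.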
